A study of Mus musculus with 12 samples.

How the data were processed

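Tetramer-positive CD8 T cells were sorted from MC38 tumors and TDLN of WT mice and of mice with a CD8-specific knockout of TrIP, and libraries were made with a stranded polyA mRNA kit. The analysis used 12 libraries in 4 groups of 3, grouped by the tissue and genotype their labels give. The labels share replicate numbers between tissues without stating that a number is 1 mouse, so libraries were treated as unpaired.

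The signal values were used as deposited: per the file headers they are normalized counts exported from Partek, 1 column per library, for 26962 Ensembl genes, of which 15456 are protein-coding and 89 have no symbol. The values themselves show what was done to make them. Each column is an estimated read count per gene divided by 1 size factor, since over 16558 genes above 0 in all libraries each column has the same median ratio to the gene-wise mean, 1.026. Between 87.0% and 89.6% of values under 50 reads are whole multiples of the value of a single read, within 0.01 reads. The rest are fractions of reads, so models for whole counts were not used. The builds GRCm38 and GRCm39 are named by the authors without their roles, and the aligner and quantifier are not given in the sources used here. The column totals and the value of a single read put the depth at 18.3 M to 36.9 M reads in genes per library.

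Genes with a mean of at least 1 CPM, taken from the mean column total, were kept, which left 16065. A pseudocount of 1 CPM, 24.9 normalized counts, was added before taking log2. One limma model (limma 3.58.1 in R 4.3.3) with a mean per group was fitted to the 12 libraries with an intensity trend, with 8 residual and 4.47 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and the threshold was 0.05. Intervals of 95% used the quantile 2.17 of the moderated distribution. The comparisons were KO against WT in tumor and in TDLN, tumor against TDLN in WT and in KO, and the interaction, which is the genotype difference in tumor minus that in TDLN. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

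For 30 gene lists, 752 of 762 symbols were found, 1 of them through an older symbol. The lists cover PI3K pathway components, FOXO1 target genes, T-cell states, proliferation, stress, metabolism, trafficking and markers of other cells. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. A list is described as called where the preset-correlation test passed. Members of a list are counted as rising or falling where they passed the threshold over all genes, unless stated otherwise.

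The design, lists, settings and rule for named genes were fixed before the data were examined. The rule takes Pik3ip1 in every comparison and, in each direction, the 10 largest log2 fold changes among genes past the threshold whose groups do not overlap. Where fewer passed, up to 5 genes of smallest p are given as values. It adds up to 4 passing members of each list, or 2 members as values where a list was called without any, and a fixed set of T-cell genes in the genotype comparisons. Predicted genes, mitochondrial genes and antigen-receptor segments are skipped in the naming by fold, which left out 874 genes in WT and 1150 in KO in the tissue comparisons. The text gives a selection of the genes this rule names.

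Under 28 settings the analysis was repeated with other scalings, pseudocounts, filters, thresholds and sample weights, with only the compared groups, with a replicate block and without each library in turn. Settings for libraries with Xist and for macrophage transcripts were added after the data were seen. Recovery was tested on simulated data, with changes of 1.5-fold, 2-fold and 4-fold divided evenly among 200 genes.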

Results

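RNA was sequenced from CD8 T cells that bound an Rpl18 tetramer, a reagent that marks T cells by the peptide their receptor recognizes. The cells were sorted on day 10 after injection of MC38, a mouse colon carcinoma line, from the tumor and from the tumor-draining lymph node (TDLN). Mice were wild type (WT) or carried a CD8-specific knockout (KO) of TrIP, the transmembrane PI3K inhibitor encoded by Pik3ip1. The 4 groups held 3 libraries each: WT TDLN, KO TDLN, WT tumor and KO tumor. Values were normalized counts for 26962 genes, with column totals between 22113970 and 26490590 and an estimated 18.3 M to 36.9 M reads in genes per library. The 3 WT libraries of each tissue are numbered 1, 3 and 4, and the 3 KO libraries 1, 2 and 3. The leading principal component held 63.4% of the variance and parted tumor from TDLN. On the next component, with 8.2%, WT tumor replicate 3 stood apart at -77.4, against -5 to 23.7 in the other tumor libraries.

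The TDLN libraries labelled KO did not hold less Pik3ip1 transcript than the WT libraries. Pik3ip1 (ENSMUSG00000034614; GRCm38 chromosome 11, 3330401 to 3342971, plus strand, from a reference annotation not established as the one behind the table) stood at 845.5 ± 244.3 normalized counts (SD, n = 3) in WT TDLN and 1146 ± 378.3 in KO TDLN. The difference was 0.42 on the log2 scale (SE 0.35, 95% interval -0.33 to 1.17, limma adjusted p = 1). In tumor the transcript stood at 145.2 ± 30.8 in WT and 108 ± 60.0 in KO, a log2 difference of -0.44 (SE 0.35, 95% interval -1.19 to 0.31, adjusted p = 0.814). Pik3ip1 was 5.03-fold lower in tumor than in TDLN in WT (log2 -2.33, SE 0.35, adjusted p = 0.00053) and 9.13-fold lower in libraries labelled KO (log2 -3.19, SE 0.35, adjusted p = 4.28e-05). The genotype difference in tumor minus that in TDLN was -0.86 (SE 0.49, adjusted p = 1). Whole-gene values do not see a deletion of single exons that leaves the rest of the transcript, so KO is used below as the label of the libraries.

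**Figure D1:**
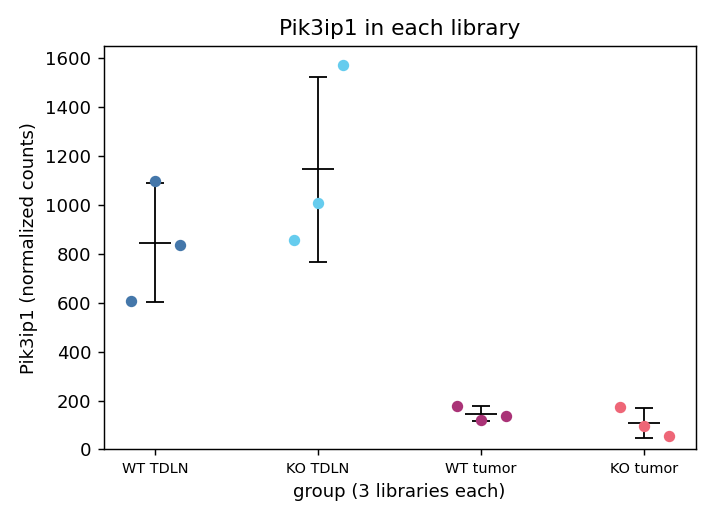
Pik3ip1 in each of the 12 libraries, in normalized counts, by group; points are libraries, the long bar is the mean and the whiskers are 1 SD (n = 3). The TDLN libraries labelled KO range from 854 to 1573 against 607 to 1095 in WT, and the highest of the 6 tumor libraries stands at 179.

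The comparison of KO with WT in tumor asks whether tumor-infiltrating T cells labelled TrIP knockout differ from WT in their transcripts. No single gene passed the threshold. Among transcripts of T-cell state, Gzmb, a cytotoxic granule protease, stood at 26462 ± 13579 normalized counts (SD, n = 3) in WT and 34196 ± 17894 in KO, and Ifng, the cytokine interferon gamma, at 46688 ± 56916 and 31752 ± 12967. The WT mean of Ifng rests on WT tumor replicate 3, at 111942 against 7286 and 20837 in the others, and on the log2 scale the difference was 0.23 (SE 0.70, adjusted p = 0.957), higher in KO. Pdcd1, which encodes PD-1, stood at 4997 ± 255.6 and 3936 ± 528.4, Havcr2 (TIM-3) at 3188 ± 334.5 and 2964 ± 706.8, and Tox, an exhaustion factor, at 1839 ± 958.8 and 990.9 ± 500.5. Tcf7, a factor of stem-like T cells, stood at 363.1 ± 327.2 and 418.4 ± 97.9, and Mki67, a proliferation marker, at 2930 ± 2081 and 3331 ± 1019. Among the T-cell genes fixed beforehand and given here, the log2 difference lay between -0.86 for Tox (SE 0.50, adjusted p = 0.803) and 0.71 for Tcf7 (SE 0.64, adjusted p = 0.828). The others were Klf2 at 0.23, Il7r at -0.52 and Tbx21 at -0.32, with adjusted p from 0.823 to 0.882. The smallest adjusted p was 0.328, shared by Fam217b (log2 1.92, SE 0.32), Klra5 (1.88, SE 0.32), an NK-type receptor, and Alox8 (2.12, SE 0.38), a lipoxygenase. Among the genes named for lower values in KO, the lowest p belonged to Strn (log2 -0.70, SE 0.16, adjusted p = 0.586).

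Gene lists were tested in the tumor comparison by camera with a preset correlation of 0.01. Of 30 lists, 10 were called, and each had adjusted p = 0.72 with an estimated correlation. None of their members passed over all genes; adjusted over the list alone, 10 of the 28 mitochondrially encoded genes, 1 of 40 cell-cycle genes and 1 of 12 glucocorticoid response genes did, as did 1 of 5 neutrophil markers, a list that was not called. Mitochondrially encoded transcripts had a median log2 fold change of 0.60 (adjusted p = 2.1e-12), with 26 of 28 members above 0. Sterol and fatty acid synthesis stood at 0.42 (adjusted p = 1.8e-05), with Cyp51, a cholesterol synthesis enzyme, at 1143 ± 328.3 normalized counts in WT and 2094 ± 80.4 in KO (SD, n = 3); without KO tumor replicate 3 its median was 0.27. CD8 T-cell identity genes stood at -0.33 (adjusted p = 5.8e-05), with 1 of 16 members above 0 and Cd8a at 30091 ± 6953 and 19731 ± 2164. Cell-cycle genes stood at 0.42 (adjusted p = 2.1e-06), with 37 of 40 above 0 and E2f1, a driver of S-phase entry, at 66.6 ± 19.3 and 191.6 ± 48.9. The cell-cycle call ended without WT tumor replicate 3 (median 0.045, adjusted p = 0.344), and its median was 0.85 without WT tumor replicate 1.

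Of the 9 lists of markers of other cells, macrophage and NK-cell markers were called in the tumor comparison and the others were not. All 20 macrophage and monocyte markers lay above 0 in KO tumor against WT tumor, with a median of 0.61 (adjusted p = 1.8e-05; adjusted p = 0.72 with an estimated correlation). That call ended without KO tumor replicate 2 (median 0.22, adjusted p = 0.18) or WT tumor replicate 4 (median 0.43, adjusted p = 0.0992), and the median was 0.94 without KO tumor replicate 3. NK-cell markers had a median of 0.71 (adjusted p = 0.0031), which ended without WT tumor replicate 4 (adjusted p = 0.154). Ribosomal proteins had a median of 0.12 (adjusted p = 0.0032), which ended without WT tumor replicate 1 (adjusted p = 0.122) or KO tumor replicate 2 (adjusted p = 0.114), and was 0.19 without KO tumor replicate 3. Dissociation and heat shock (0.29), ATF4 and amino acid response (0.24) and glucocorticoid response (0.28) each had adjusted p = 0.044. The heat shock call ended without WT tumor replicate 1 (median 0.095), WT tumor replicate 4 (0.22) or KO tumor replicate 2 (0.165). The ATF4 call ended without WT tumor replicate 3 (0.12), WT tumor replicate 4 (0.12), KO tumor replicate 2 (0.18) or KO tumor replicate 3 (0.12). The glucocorticoid call ended without WT tumor replicate 1 (0.17), KO tumor replicate 1 (0.29) or KO tumor replicate 2 (0.28), and the median was 0.46 without WT tumor replicate 4. All of these had adjusted p = 0.72 with an estimated correlation.

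In tumor, limma called 0 of 16065 genes, and 1004 had an unadjusted p under 0.05, against 803 given by chance. This excess depended on the fit. The model pools the spread of both tissues, whose median residual SD on the log2 scale was 0.416 in tumor and 0.269 in TDLN. With only the compared groups in the fit, 468 genes had an unadjusted p under 0.05. Groups did not overlap in 7.5% of genes, where chance gives 10%. The count was 10, all higher in KO, without WT tumor replicate 1, and 6 with no filter on low values. The 10 included Spp1, of the macrophage list, and Cxcl2, of the neutrophil list. Spp1 stood at 5524 normalized counts in the left-out library, 953 and 1166 in the other WT tumor libraries and 3264 to 5976 in KO tumor. Whether RNA from other cells lies behind these calls was not tested. In simulated data with 200 changed genes divided evenly among changes of 1.5-fold, 2-fold and 4-fold, 1.5%, 10.4% and 60.6% of them were recovered, and 13 of all 61 calls were false.

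The same comparison in TDLN asks whether the genotypes differ in the node that drains the tumor, sampled on the same day. B-cell markers were the list that shifted most: all 11 lay above 0 in libraries labelled KO, with a median log2 fold change of 0.85 (camera adjusted p = 4.2e-13; adjusted p = 0.16 with an estimated correlation). Ms4a1, which encodes CD20, stood at 142.1 ± 12.6 normalized counts in WT and 389.3 ± 257.8 in KO (SD, n = 3), and Ighd, the IgD heavy chain, at 505.5 ± 233.3 and 1195 ± 523.2. Mitochondrially encoded transcripts had a median of 0.20 (adjusted p = 7.1e-07) and ribosomal proteins 0.15 (adjusted p = 4.3e-12). Sterol and fatty acid synthesis had a median of -0.32 (adjusted p = 9.3e-08), with Sqle, a cholesterol synthesis enzyme, at 433.7 ± 72.7 in WT and 251.8 ± 98.0 in KO. Naive and stem-like genes had a median of 0.25 (adjusted p = 0.0012), with Lef1 at 2228 ± 826.6 and 3795 ± 1928, and FOXO1 target genes 0.19 (adjusted p = 0.045). PI3K pathway components had a median of -0.12 (adjusted p = 0.0051), with 5 of 25 members above 0. ATF4 response (-0.14, adjusted p = 0.005), glycolysis (-0.17, adjusted p = 0.015) and heat shock (-0.06, adjusted p = 0.044) also lay below 0. Apart from B-cell markers, these calls had adjusted p between 0.51 and 0.62 with an estimated correlation, and 0 members of any list passed, over all genes or adjusted over the list alone.

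Of those TDLN lists, only B-cell markers kept their call without each of the 6 libraries in turn, with medians from 0.61 without KO TDLN replicate 3 to 1.08 without KO TDLN replicate 1. Without WT TDLN replicate 3 the mitochondrial (median 0.08, adjusted p = 0.0553) and ribosomal (0.04, adjusted p = 0.082) calls ended, and the mitochondrial median was 0.32 without WT TDLN replicate 1. The sterol call ended without WT TDLN replicate 4 (-0.06, adjusted p = 0.249), and its median was -0.17 without KO TDLN replicate 3 and -0.49 without WT TDLN replicate 3. The FOXO1 list turned to -0.16 without KO TDLN replicate 3 and -0.01 without WT TDLN replicate 4, and stood at 0.34 without KO TDLN replicate 1 and 0.31 without KO TDLN replicate 2. The naive call ended without KO TDLN replicate 3 (0.13) or WT TDLN replicate 4 (0.10), and its median was 0.51 without KO TDLN replicate 2 and 0.54 without WT TDLN replicate 3. The PI3K call ended without KO TDLN replicate 1 (-0.10, adjusted p = 0.161). The ATF4 call ended without KO TDLN replicate 3 (-0.01), WT TDLN replicate 3 (-0.12) or WT TDLN replicate 4 (-0.09), and its median was -0.23 without KO TDLN replicate 1 and -0.215 without KO TDLN replicate 2. The glycolysis call ended without the same libraries as ATF4 (-0.05, -0.12 and -0.15) and stood at -0.29 without WT TDLN replicate 1. The heat shock call ended without KO TDLN replicate 2 (-0.085) or 3 (-0.10) or WT TDLN replicate 3 (-0.10) or 4 (-0.14), and was -0.12 without KO TDLN replicate 1 and -0.23 without WT TDLN replicate 1.

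Among the single genes named in TDLN, the smallest unadjusted p with higher values in KO belonged to Ly86 (30.7 ± 10.9 against 135.7 ± 74.0 normalized counts, SD, n = 3) and H2-Ob (122.9 ± 28.3 against 333.3 ± 182.7), a class II antigen-presentation gene of B cells, was among the 5 lowest. Cx3cr1, a receptor of effector T cells, stood at 310.2 ± 141.5 in WT and 140.6 ± 52.8 in KO, and Car2 at 699.1 ± 102.9 and 313.6 ± 109.6. Among T-cell genes fixed beforehand, Tcf7 (2759 ± 1033 and 3197 ± 1189), Gzmb (6381 ± 4577 and 5320 ± 3994), Pdcd1 (803.9 ± 379.2 and 605.4 ± 194.6), Mki67 (12275 ± 1853 and 11093 ± 1535), Tbx21 (626.8 ± 162.1 and 449.5 ± 42.9) and Ifng (316 ± 102.4 and 375.5 ± 15.4) had log2 differences from -0.43 for Tbx21 to 0.27 for Ifng, each with adjusted p = 1. The limma test called 0 of 16065 genes, with 123 at an unadjusted p under 0.05 and a smallest adjusted p of 1. With only the compared groups in the fit, 367 genes had an unadjusted p under 0.05. Groups did not overlap in 6.3% of genes, where chance gives 10%, and in simulated data made the same way 4.5% of the genes changed 2-fold and 59.1% of those changed 4-fold were recovered.

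Tumor was compared with TDLN in each genotype to show how tetramer-positive cells of the same specificity differ between the tissues. In WT, 4312 genes differed, 2560 higher and 1752 lower in tumor. In libraries labelled KO, 4919 differed, 2902 higher and 2017 lower. The genotypes shared 2086 of the higher genes, where 462 would be shared by independence, and 1171 of the lower genes, where 220 would be; 0 genes were called in opposite directions. Across genes, which are not independent replicates, the tumor-TDLN differences of the genotypes had Pearson r = 0.905 and Spearman rho = 0.853. The balance of directions depended on scaling. With values rescaled to a common column total the counts were 2110 higher and 2527 lower in WT and 2644 and 2403 in KO, and with quantile normalization 2018 and 2285 in WT and 2396 and 2870 in KO. The median log2 difference of all genes moved from 0.05 to -0.11 and -0.09 in WT, and from 0.05 to -0.02 and -0.12 in KO. Without KO TDLN replicate 1 the KO count was 3056, with 2026 higher and 1030 lower. In WT, 1841 were higher and 1085 lower without WT TDLN replicate 4. Groups did not overlap in 39.8% of genes in WT and 50.2% in KO, where chance gives 10%.

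Early transcripts that the T-cell receptor can induce, and effector transcripts, were higher in tumor. Of these early genes, 6, Fosb among them, are also in the dissociation and heat shock list. Tissue dissociation and RNA from other cells stay open as causes of the rise in early genes. Of 30 early genes induced by the T-cell receptor, 25 rose in WT and 24 in KO, with list medians of 3.35 and 3.09 on the log2 scale. Nr4a2, an orphan nuclear receptor induced by receptor signaling, rose from 67.4 ± 25.5 to 23883 ± 7085 normalized counts in WT (log2 8.01, SE 0.35, adjusted p = 4.58e-08) and from 65.1 ± 36.5 to 23212 ± 8133 in KO (log2 8.05, SE 0.35, adjusted p = 3.69e-08; SD, n = 3). Nr4a3 rose by 6.64 and 5.74, and Fosb, a subunit of AP-1, by 6.64 and 6.94. Of 30 effector and cytotoxic genes, 22 rose and 1 fell in WT and 23 rose and 2 fell in KO, with medians of 2.23 and 2.72. Zeb2, a factor of effector differentiation, rose by 4.96 and 4.97, Serpinb9, which shields cells from granzyme B, by 3.49 in both, and the receptor chain Klrd1 by 3.51 and 3.88. Of 27 inhibitory receptor and exhaustion genes, 17 rose and 1 fell in WT and 16 rose and 2 fell in KO (medians 2.01 and 2.16), among them Rgs16 by 5.84 and 6.22. Of 16 tissue residency genes, 8 rose and 2 fell in WT and 9 rose and 3 fell in KO (medians 1.28 and 1.10). Rgs2 rose by 5.61 and 5.99 and Crem by 5.32 and 5.67. Itgae, an integrin chain on the same list, lay lower in tumor in both genotypes. In WT its highest tumor value was 129 normalized counts and its lowest TDLN value 320. In KO these values were 74.8 and 406. The folds given here carry a pseudocount of 24.9 normalized counts, so they understate changes of genes near 0 in TDLN.

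By camera, early genes had adjusted p = 9.8e-20 in WT and 5.3e-17 in KO, effector genes 5.6e-08 and 6.9e-09, exhaustion genes 2.0e-06 and 6.1e-06, and residency genes 0.0058 and 0.012. With an estimated correlation the adjusted p for these lists was 0.073, 0.073, 0.086 and 0.086 in WT and 0.062, 0.062, 0.088 and 0.088 in KO. The rotation test fry, which asks whether a list's genes move on balance to 1 side, gave adjusted p from 2.8e-06 to 1.2e-05 in WT and from 2.0e-06 to 1.1e-05 in KO. Beside these lists, the macrophage and monocyte markers summed to 0.086% to 0.33% of all values in the tumor libraries against 0.012% to 0.024% in TDLN. That is the share of the listed marker genes alone and not an estimate of RNA from other cells. The CD8 T-cell identity list held 0.584% to 0.877% of all values in the same tumor libraries.

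Cell-cycle transcripts and several homing and naive-cell transcripts were lower in tumor. All 40 cell-cycle genes passed the threshold as lower in WT and 25 of 40 in KO, where 1 of 40 lay above 0. Adjusted over the list alone, 32 passed as lower in KO. The list medians were -1.66 (camera adjusted p = 3.7e-20) in WT and -1.11 (camera adjusted p = 3.3e-12) in KO. With an estimated correlation the camera adjusted p was 0.16 and 0.23. Aurka, a mitotic kinase, fell from 1823 ± 456.9 to 264.1 ± 58.7 normalized counts in WT and from 1523 ± 478 to 285.9 ± 69.5 in KO (SD, n = 3), and Tyms, a thymidylate synthesis enzyme, fell as well (log2 -2.10 and -1.87). Naive and stem-like genes moved both ways (5 rose and 6 fell of 20 in WT, 3 and 4 in KO; camera adjusted p = 0.44 and 0.24). Within that list Id3, a transcriptional regulator, fell (log2 -3.09 in WT, SE 0.49, adjusted p = 0.000745, and -3.94 in KO, SE 0.49, adjusted p = 0.000115), while Satb1 rose by 2.12 and 1.74. FOXO1 target genes also moved both ways (6 rose and 5 fell of 23 in WT, 5 and 3 in KO; adjusted p = 0.67 and 0.49): Klf2, which controls exit from tissue, fell (-2.14 and -1.94), while Bcl2l11, which encodes the death factor BIM, rose by 3.24 and 3.68. Of 22 homing and chemokine receptor genes, 4 rose and 7 fell in WT and 6 rose and 7 fell in KO (adjusted p = 0.13 and 0.30). Cxcr3, a receptor for interferon-induced chemokines, fell (-3.34 and -3.19), the integrin chain Itgb7 fell (-2.87 and -2.55), and Cx3cr1 rose by 1.87 and 2.86. Wnt10a, a secreted signaling protein, fell (-4.62 and -3.92).

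Lists of glycolysis and hypoxia, heat shock, glucocorticoid response, apoptosis, IL-2 response and mitochondrially encoded genes were called higher in tumor in both genotypes. Some share members with other lists: 7 of 21 heat shock, 4 of 12 glucocorticoid, 4 of 23 apoptosis and 8 of 22 IL-2 genes. Dusp1 is also in the early gene list and Fasl in the effector list, so these calls are not independent of those above. Glycolysis and hypoxia genes rose in 12 of 30 in WT, where 1 fell, and 15 in KO (medians 0.30 and 0.83, adjusted p = 0.0025 and 8.6e-06; 0.29 and 0.12 as adjusted p with an estimated correlation), with Hilpda, a hypoxia-induced lipid-droplet protein, up by 3.72 and 3.41. Dissociation and heat shock genes rose in 14 of 21 in WT, where 2 fell, and 13 in KO (medians 2.18 and 2.38, adjusted p = 4.4e-07 and 3.9e-09; adjusted p = 0.086 and 0.062 with an estimated correlation), with Atf3 up by 5.37 and 5.94. Glucocorticoid response genes rose in 8 and 9 of 12, where 1 fell in each (medians 1.32 and 1.81, adjusted p = 0.00056 and 3.1e-05; adjusted p = 0.086 and 0.064 with an estimated correlation), with the phosphatase Dusp1 up by 4.78 and 5.40. Apoptosis regulators rose in 10 of 23 in both (medians 0.72 and 0.80, adjusted p = 0.0066 and 0.0041; adjusted p = 0.16 and 0.12 with an estimated correlation), with Fasl up by 3.25 and 2.88; the KO median was 0.52 without KO TDLN replicate 3. IL-2 and STAT5 response genes rose in 7 and 11 of 22, where 1 and 2 fell (medians 0.73 and 0.96, adjusted p = 0.014 and 0.0066; adjusted p = 0.43 and 0.35 with an estimated correlation). In WT that call ended without WT TDLN replicate 1 (adjusted p = 0.054) or WT tumor replicate 3 (adjusted p = 0.101), and the median was 1.12 without WT tumor replicate 1. Mitochondrially encoded genes rose in 16 and 21 of 28 (medians 0.80 and 1.16, adjusted p = 2.3e-08 and 4.4e-10; adjusted p = 0.27 and 0.20 with an estimated correlation). The mitochondrial genes of smallest p encoded transfer RNAs, with mt-Ta up by 3.58 and 4.50. Macrophage markers were higher in the same tumor libraries, where the listed genes alone summed to up to 0.33% of all values, against at most 0.024% in TDLN.

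The macrophage, fibroblast and endothelial, neutrophil and NK-cell marker lists were called higher in tumor, and the B-cell list lower. Macrophage and monocyte markers rose in 18 of 20 in WT and 19 in KO (medians 4.12 and 4.60, adjusted p = 1.1e-16 and 3.1e-18; adjusted p = 0.086 and 0.066 with an estimated correlation). Lyz2, lysozyme M, stood at 22.1 ± 25.8 normalized counts in WT TDLN and 10839 ± 6695 in WT tumor, and at 14.8 ± 6.67 and 16553 ± 11730 in KO (SD, n = 3). The monocyte chemokine Ccl2 was listed at 0 in every TDLN library and stood at 5225 ± 1172 in WT tumor and 7525 ± 1618 in KO tumor. Fibroblast and endothelial markers rose in 8 and 7 of 14 (medians 3.04 and 3.01, adjusted p = 3.7e-05 and 2.4e-05; adjusted p = 0.30 and 0.27 with an estimated correlation), with a WT median of 1.63 without WT tumor replicate 4. Col3a1, a fibroblast collagen, was listed at 0 in TDLN and stood at 7564 ± 6730 and 5591 ± 2597 in tumor. Neutrophil markers rose in 5 of 5 in both (medians 3.20 and 2.90, adjusted p = 0.0013 and 0.0011; adjusted p = 0.073 and 0.062 with an estimated correlation). These included Cxcl2 and Il1r2, which other cells also express, while the neutrophil gene S100a9, looked at after its values were seen, lay between 0 and 67.9 in the tumor libraries. NK-cell markers rose in 5 of 10 in both, where 1 fell (medians 2.21 and 2.44, adjusted p = 0.023 and 0.0014; adjusted p = 0.23 and 0.088 with an estimated correlation), and the WT call ended without WT tumor replicate 3 (adjusted p = 0.0637). The NK list's rising members include Tyrobp and Fcer1g, which macrophages also express, and Ncr1, an NK receptor looked at after its values were seen, was listed at 0 in 5 tumor libraries and at 4.12 in the other. Klrb1c stood at 46.3 ± 19.2 in WT TDLN and 5.99 ± 7.68 in WT tumor. In KO its values overlapped, at 19.7 to 76.8 in TDLN and 12.5 to 125 in tumor. B-cell markers fell in 7 and 10 of 11 (medians -1.79 and -2.58, adjusted p = 4.0e-06 and 3.3e-09; adjusted p = 0.14 and 0.067 with an estimated correlation), and Ms4a1 stood at 3.78 ± 6.54 and 0.423 ± 0.733 in tumor.

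**Figure D2:**
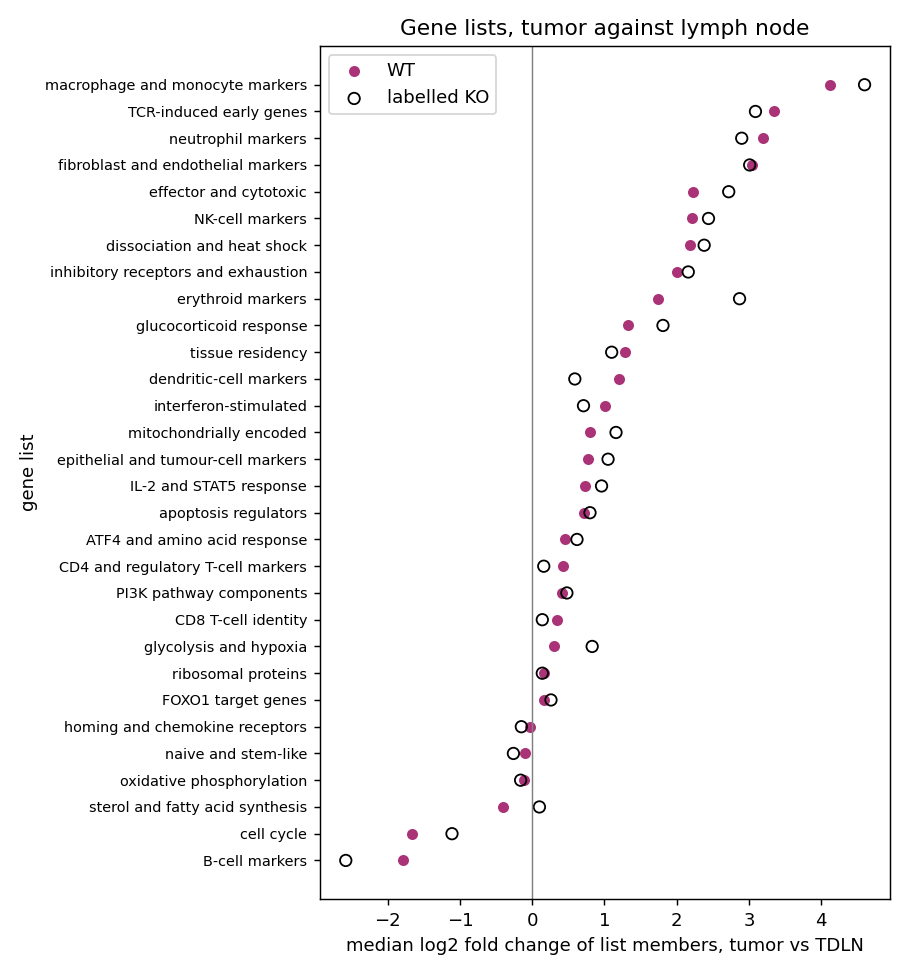
Median log2 fold change, tumor against TDLN, of the measured members of each of the 30 gene lists, with filled points for WT and open circles for libraries labelled KO. Macrophage and monocyte markers lie at 4.12 and 4.60, early genes at 3.35 and 3.09, and B-cell markers at -1.79 and -2.58.

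**Figure D3:**
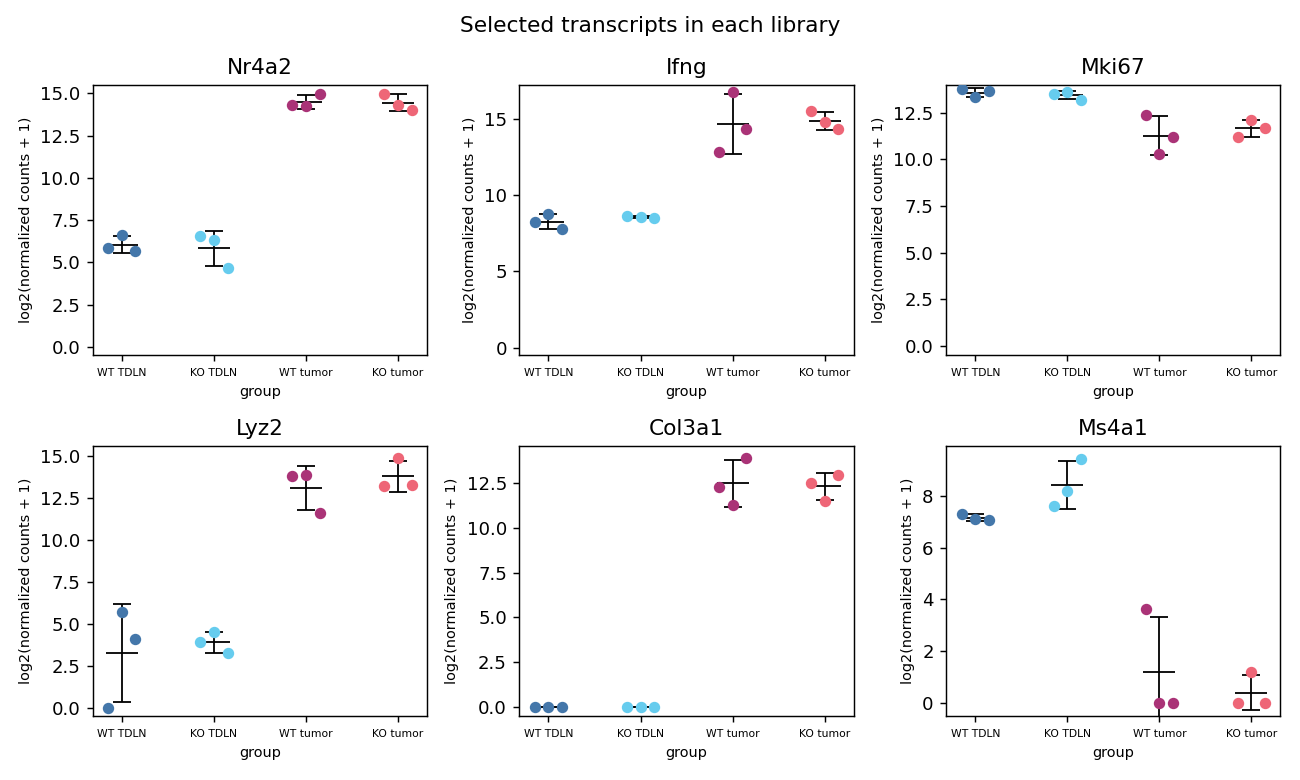
Levels of 6 transcripts in each library as log2 of normalized counts plus 1, by group; points are libraries, long bars are means and whiskers 1 SD of the plotted values (n = 3). Nr4a2, Ifng, Lyz2 and Col3a1 lie higher in all 6 tumor libraries than in TDLN, and Mki67 and Ms4a1 lie lower.

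The remaining lists were called in 1 genotype or in neither, and a call in 1 genotype alone does not show that the genotypes differed. None of the 4 lists called in 1 genotype alone, other than sterol synthesis and the ATF4 response, was called in the interaction. Interferon-stimulated genes had a median of 1.01 in WT (adjusted p = 0.0025; 0.64 as adjusted p with an estimated correlation), which ended without WT TDLN replicate 4 (median 0.52, adjusted p = 0.107), and 0.71 in KO (adjusted p = 0.067). Sterol synthesis had a median of -0.40 in WT (adjusted p = 0.049; 0.65 as adjusted p with an estimated correlation), which ended without WT TDLN replicate 4 (-0.255), WT tumor replicate 3 (-0.53) or WT tumor replicate 4 (-0.315), and 0.10 in KO (adjusted p = 0.15). PI3K pathway components rose in 9 of 25 in both genotypes, with medians of 0.41 (adjusted p = 0.093) and 0.48 (adjusted p = 0.0083; 0.22 as adjusted p with an estimated correlation). Phlpp1, a phosphatase that acts on AKT, rose by 2.56 and 2.52, and Pik3ap1, an adaptor of PI3K, by 2.04 and 2.51. The ATF4 and amino acid response rose in 12 of 29 in both, where 4 and 2 fell, with medians of 0.45 (adjusted p = 0.13) and 0.62 (adjusted p = 0.0031; 0.35 as adjusted p with an estimated correlation), and Slc38a2, an amino acid transporter, rose by 2.33 and 2.35. Oxidative phosphorylation (-0.12 and -0.16), CD8 T-cell identity (0.34 and 0.14), CD4 and regulatory T-cell (0.42 and 0.16), dendritic-cell (1.20 and 0.59), epithelial and tumor-cell (0.77 and 1.05), erythroid (1.74 and 2.87) and ribosomal (0.17 and 0.14) lists were not called in either, with adjusted p from 0.052 to 0.99. The ribosomal list's median in WT turned to -0.004 with values rescaled to a common column total, and the CD4 list's median was -0.20 in KO with quantile normalization.

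The test of whether the genotype difference itself differed between the tissues called no gene. The limma interaction gave 0 of 16065 genes, 465 with an unadjusted p under 0.05 and a smallest adjusted p of 1. The lowest p belonged to Alox8 (log2 2.46, SE 0.53, adjusted p = 1), which stood at 320.5 ± 75.4 normalized counts in WT tumor, 1506 ± 476.4 in KO tumor, 20.9 ± 20.6 in WT TDLN and 10.5 ± 12.8 in KO TDLN (SD, n = 3). With no filter on low values 1 gene passed, Mexis. Camera called 11 of 30 lists, and with an estimated correlation their adjusted p lay between 0.47 and 0.65. Sterol and fatty acid synthesis lay 0.68 higher in the tumor difference than in the TDLN difference (adjusted p = 1.6e-11; 0.47 as adjusted p with an estimated correlation), and B-cell markers lay at -1.17 (adjusted p = 2.6e-07; 0.47 as adjusted p with an estimated correlation). Some B-cell markers lay near 0 in tumor, which limits what their genotype difference there can show. Across genes, the genotype differences in tumor and TDLN had Pearson r = 0.053 and Spearman rho = 0.088.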

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

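These results stand here because a list's genotype difference in tumor differed from that in TDLN by the interaction test, which was planned. No gene passed in that test, and with an estimated correlation none of the 11 lists did. For each list the value is the median log2 difference, followed by the camera adjusted p.

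Sterol and fatty acid synthesis stood at 0.68 (adjusted p = 1.6e-11), from 0.42 in tumor and -0.32 in TDLN. B-cell markers stood at -1.17 (adjusted p = 2.6e-07), from -0.16 in tumor and 0.85 in TDLN. Macrophage and monocyte markers stood at 0.78 (adjusted p = 1.1e-05), from 0.61 and -0.03, and at 0.298 without KO tumor replicate 2. Of their 20 members, 5 exceeded 1 CPM in TDLN, so low values limit what the TDLN difference can show. The ATF4 and amino acid response stood at 0.36 (adjusted p = 0.00053), from 0.24 and -0.14, and at 0.209 without KO TDLN replicate 3. Cell-cycle genes stood at 0.53 (adjusted p = 2.6e-07), from 0.42 and -0.10; the call ended without WT tumor replicate 3 (0.112), and the median was 0.978 without WT tumor replicate 1. CD8 T-cell identity genes stood at -0.32 (adjusted p = 0.00068), from -0.33 and -0.02; the call ended without KO tumor replicate 3 (-0.234), and the median was -0.526 without WT TDLN replicate 3 and -0.175 without WT TDLN replicate 4. Mitochondrially encoded genes stood at 0.40 (adjusted p = 0.00087), from 0.60 and 0.20. That call ended without WT TDLN replicate 1 (0.312) or WT tumor replicate 1 (0.309), and the median was 0.216 without WT tumor replicate 3 and 0.657 without WT tumor replicate 4.

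Dissociation and heat shock genes stood at 0.35 (adjusted p = 0.0015), from 0.29 and -0.06, and the call ended without KO tumor replicate 2 (0.24) or WT tumor replicate 1 (0.299). Glycolysis and hypoxia genes stood at 0.35 (adjusted p = 0.0031), from 0.16 and -0.17; the call ended without KO tumor replicate 2 (0.244) or WT tumor replicate 4 (0.209), and the median was 0.195 without KO TDLN replicate 3. Glucocorticoid response genes stood at 0.43 (adjusted p = 0.0086), from 0.28 and -0.05, and the call ended without WT tumor replicate 1 (0.254). NK-cell markers stood at 0.97 (adjusted p = 0.016), from 0.71 and -0.07. Their call ended without KO TDLN replicate 1 (0.703), KO tumor replicate 1 (0.892), KO tumor replicate 2 (0.795), WT TDLN replicate 4 (0.787) or WT tumor replicate 4 (0.713). With an estimated correlation the adjusted p was 0.47 for 9 of these lists, 0.59 for cell-cycle genes and 0.65 for mitochondrially encoded genes, and by fry it lay between 0.62 and 0.73.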

How the results depend on the processing

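Settings on libraries with Xist and on macrophage transcripts were chosen after seeing the data. No named gene that passed the test changed direction. KO against WT in tumor gave 6 genes with no filter on low values, and 0 to 10 when each replicate was left out, with 10 without WT tumor replicate 1; KO against WT in TDLN gave 0 in every setting run. Tumor against TDLN in KO gave 3056 without KO TDLN replicate 1 and up to 4828 without others, and the interaction gave 1 gene with no filter. In WT that tissue count stayed within 1.5 times the value reported in all settings run, from 2897 to 5689. The genes lower in tumor varied more, from 1752 as reported to 1052 with only the compared groups in the fit. With a replicate block the counts were 0, 0, 4076, 4647 and 0, in the order tumor, TDLN, tissue in WT, tissue in KO and interaction; deviations of same-numbered libraries from their group means correlated at -0.04 to 0.20, and 2 of 6 fitted their own number best, while Xist marks the libraries numbered 3 in both tissues of both genotypes. Whether a number is a mouse or a pool is left open. In tumor, without libraries with Xist, TCR-induced early genes turned to 0.225 (camera adjusted p = 0.0251) and fibroblast and endothelial markers to -0.616 (camera adjusted p = 0.0184). With the macrophage list as covariate, macrophage and monocyte markers turned to -0.045 and erythroid markers to -1.299 (camera adjusted p = 0.0439). The early-gene, fibroblast and erythroid lists were not called in the main fit. In TDLN, without libraries with Xist, FOXO1 target genes turned to -0.065, and glycolysis and hypoxia shrank to -0.009, where the direction of its set test turned but its median did not. Without single replicates in TDLN, FOXO1 target genes ranged from -0.156 to 0.341 and interferon-stimulated genes, not called with all libraries, from -0.273 without WT TDLN replicate 4 (adjusted p = 0.000273, a call toward lower) to 0.821 without WT TDLN replicate 3, a call toward higher. WT TDLN replicate 3 held 0.455% of its values in that list, against 0.144% to 0.236% in the other TDLN libraries. In the interaction, ribosomal proteins turned to 0.085 with quantile normalization (camera adjusted p = 0.0166) and 0.083 without libraries with Xist (camera adjusted p = 0.00642). Fibroblast and endothelial markers turned to -0.631 without libraries with Xist (camera adjusted p = 0.026). Neither list was called there in the main fit. The macrophage covariate is built from the list it turned, and the filter changes which genes are tested; for the others the cause was not tested. The fits with edgeR and DESeq2 were not run, since the values are not whole reads. At this spread, simulated changes of 1.5-fold were recovered in 0% to 1.5% of cases.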

Other observations

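The tests of scaling, of Y-linked transcripts, of dissociation and of the splits of the 3 comparisons with no gene passing were chosen after the results were seen, as were the variable segments, the sex-linked genes and Mexis.

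T-cell receptor variable segments differed between libraries. The leading beta segment took 21.4% to 87.8% of the reads in beta segments, with a median of 48.95%, and 4 different segments led in the 12 libraries. Trbv20 took 87.8% in WT tumor replicate 1 (95% Wilson interval 87.1 to 88.4), Trbv31 took 82.9% in WT TDLN replicate 4 (82 to 83.8), and Trbv29 led with 21.4% in WT tumor replicate 4 (20.3 to 22.6). The leading alpha segment took 9.6% to 50.7%, with 9 segments leading. In some libraries segments of nearly the same name stood almost level, such as Trav14d-2 (33%) and Trav14n-2 (32.2%) in WT tumor replicate 1. In KO TDLN replicate 2 they did not, with Trav16n at 50.7% and Trav16 at 7.8%. Whether such pairs divide the same reads was not tested, so alpha shares are not set against beta shares. The intervals rest on estimated reads and cover counting error only. The long noncoding RNA Mexis was listed at 0 in 9 libraries and at 37.4, 49.5 and 52.7 normalized counts in the 3 KO tumor libraries.

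Macrophage and monocyte transcripts were higher in tumor libraries, although the sort was on CD8 and tetramer; Lyz2 stood at 3132 to 30096 normalized counts there against 0 to 50.4 in TDLN. Of the list's 20 members, 2 are in other lists and 5 exceed 1 CPM in TDLN. The lowest list median over both genotypes and the 3 other scalings was 3.82, so none of these scalings accounts for the difference. The median-ratio scaling repeats the deposited one, and the others moved the median of all genes from 0.05 to -0.12 at most. The test could therefore hardly have come out in favor of scaling. Across the 6 tumor libraries the members deviated together (mean correlation 0.575, against a 95th percentile of 0.0892 in 1000 matched sets, percentile 100), as RNA from other cells would have it. Genes regulated together within T cells would deviate together as well, so the test cannot tell these apart. In the camera test over all libraries, the estimated correlation was 0.60 for cell-cycle genes and 0.46 for macrophage markers. RNA from other cells stays a hypothesis, and expression by the T cells themselves in tumor, which the design names as a tissue difference, was not tested.

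Early-response transcripts were higher in tumor libraries. RNA from other cells may contribute: their mean correlation with the macrophage list was 0.0035, at percentile 44.3 of matched sets, whose median was 0.014 and 95th percentile 0.133. This lies on the side set beforehand as speaking against it, but by less than the spread of the matched sets, a requirement set after the value was seen, so it stays open. Tissue dissociation stays open as well, since tumor and TDLN were different tissues to take apart: 15 genes found in the dissociation list alone had medians of 0.67 and 0.73, against 3.12 and 2.50 for 24 found in the TCR list alone, and the 6 genes in both lists, which include Fosb, had the highest medians, 4.26 and 4.65. The tissue itself is an untested biological explanation.

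Xist stood at 2485 to 3845 in the 4 libraries numbered 3 and at most at 2.54 in the other 8, and the 2 tumor libraries among the 4 also held Y-linked transcripts, 1467 and 2477 over 4 genes against 8705 to 10651 in the other 4 tumor libraries. Reads crossing between libraries are argued against, since the highest Xist elsewhere was 2.54 where 182 would be needed. Reads of the X-linked copies are argued against, since the sum was 0 in the TDLN libraries with Xist. A male sample mixed in one way cannot be told apart from other sources: the largest over the smallest share was 1.71 in 1 library and 3.1 in the other, against up to 1.98 among the rest. No biological explanation was tested, since the groups do not name sex.

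Other splits of the same libraries bear on the counts. For KO against WT in tumor the real count was 0, so all 10 splits were as large by construction, and the highest other was 594, from WT replicates 1 and 3 with KO replicate 3 against the rest. So high a count points to a structure of the samples. On the leading principal component, the libraries of the first side lay at 40.3 to 75.4 and the rest at 77 to 90.8. What lies behind this order was not tested. For KO against WT in TDLN the real count was 0, all 10 splits were as large by construction, and the highest other was 0. For the interaction the real count was 0, all 100 drawn splits were as large by construction, and the highest other was 7. For tumor against TDLN, 1 of 10 splits, the real one, gave as many genes in each genotype: 4312 with a highest other of 1 in WT, and 4919 with a highest other of 0 in KO. With 10 splits a share under 0.05 cannot be reached.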
